A study of Mus musculus with 12 samples.

How the data were processed

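RNA was measured by sequencing in 12 libraries of Ba/F3 cells, a mouse pro-B cell line, all with NRAS G12D. Each library belongs to 1 of 4 groups by the construct the cells received: ZsGreen alone, ETV6 WT, ETV6 P214L or ETV6 I209S P214L, with 3 libraries in each. Samples are named here by group and replicate. The labels do not say whether the 3 libraries of a group are separate cultures, so they may be technical replicates, and they give no sequencing batch.

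Per the labels, RNA was selected by its poly-A tail, reads were aligned to the mouse genome build mm39 with HISAT2 2.0.5 and reads per gene were counted with featureCounts 1.5.0-p3. The protocol text describes both a directional and a non-directional library, so strandedness is not known, and values of genes that overlap on opposite strands are uncertain. The annotation release and the tool of the authors' test are not given. The deposited table holds a raw read count for each of 56748 genes in each library, of which 30009 had no count in any library, and 959 symbols belong to more than 1 gene, so genes were followed by their identifier. The deposited FPKM of a gene is its count over gene length and library total, times 1 factor per library that lay between 0.988 and 1.03. Per the file headers the table also gives the gene length in bases, the position of each gene and its biotype. The authors deposited a log2 fold change, a p-value and an adjusted p-value for 7 comparisons, which were compared with the values computed here and used for nothing else. Gene positions are those of the deposited table, since the reference at hand was of an older build.

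The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filterByExpr over the 4 groups, which left 14794 genes, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, and the 6 pairwise comparisons and a test of any difference among the 4 groups were made from it. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called changed at an adjusted p under 0.05. Every adjusted p of a gene is from this edgeR fit unless another tool is named. Levels are CPM, edgeR's scaled counts with TMM factors, given as mean ± SD of 3 libraries, and log2 fold changes carry the SE of the fit where one is printed.

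Where a group had no count of a gene, the fold is a lower bound from a floor of 3 counts over the group's libraries. Where it had 1 to 3 counts, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

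The comparisons, the gene lists, the named-gene rule and most alternatives were chosen before the data were examined. Genes were named by this rule: for ETV6 WT, P214L and their comparison and for I209S P214L against WT, the 10 largest rises and the 10 largest falls among protein-coding genes called changed, with a mean CPM of at least 5 over the compared groups and no overlap between their libraries, and 5 of each for the other two comparisons; symbols of unnamed gene models were left out. Up to 4 members of each list with the smallest adjusted p were added, and a few genes, among them Etv6, Nras, Hras, Il3 and Xpo1, were always followed. This gave 753 pairs of gene and comparison. The text gives values for part of these pairs. Where 5 or fewer genes were called, genes outside the rule were followed too, and are marked as chosen after their values were seen.

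There were 28 gene lists written by hand: interferon response, MHC class I, ETS factors, RAS-MAPK targets, STAT5 targets, IL-3 receptor axis, apoptosis, p53 targets, cell cycle, MYC and ribosome biogenesis, cholesterol, integrated stress response, glycolysis and hypoxia, oxidative phosphorylation, unfolded protein response, NF-kB, lysosome, nuclear transport, mast and basophil, neutrophil and monocyte, megakaryocyte, erythroid, stem and progenitor, B lineage, T lineage, fibroblast, mitochondrially encoded RNA and nuclear-retained RNA. The 25 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry (limma 3.58.1), with Benjamini-Hochberg adjustment over the lists. Beside each count of called members stands the count adjusted over the list alone.

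A score of likeness to ETV6 WT was, for each library, the mean centred log2 CPM (prior count 2) of the genes raised by ETV6 WT against ZsGreen minus that of the genes lowered by it. Scores of groups were compared with a two-sided exact permutation test, whose smallest possible p for 3 against 3 libraries is 0.1. The change from P214L to I209S P214L was also regressed on the change from ZsGreen to ETV6 WT over the same genes; these changes share no library. Comparisons with a shared control were set against 20 simulations without any difference between groups. Because 3 control libraries cannot be divided, part of any excess over those simulations may come from the shared control.

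The pipeline was tested on simulated counts, drawn from a negative binomial model with the fitted spread of each gene. In them 50 changes of each size were planted. These counts follow the fitted model and lack any further structure among the real libraries, so real recovery may be lower. For ETV6 WT against ZsGreen it recovered 54% of 1.5-fold changes, 70% of 2-fold, 86% of 4-fold and 96% of 8-fold changes, with 8 false calls of 176. For I209S P214L against ETV6 WT these shares were 60%, 70%, 90% and 96%, with 7 false calls of 180. A planted slope of 1 was read as 0.914, one of 0.8 as 0.740 and one of 0 as -0.006, so the planted slopes above 0 were read somewhat low. In these simulations P214L had no effect of its own, so they do not cover a part of the effect that P214L keeps.

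Alternatives changed 1 choice at a time: RLE size factors, total counts, DESeq2 1.42.0, limma-voom, no filter, a mean CPM of at least 5, protein-coding genes alone, a block for replicate number, a fit of the compared groups alone, thinning to the smallest total, and each of the 12 libraries left out in turn. Chosen after seeing the data were 4 more: leaving out the first libraries of ETV6 WT and I209S P214L, leaving out those and the first ZsGreen library, removing ribosomal RNA genes before scaling, and restricting the slope to genes above the floor in every group. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Splicing, alleles and the construct's own sequence were left out, because counts per gene do not hold them.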

Results

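Transcripts were measured in Ba/F3 cells, a mouse pro-B line that normally depends on interleukin-3 (IL-3), which all carried NRAS G12D, an active form of the RAS protein. The cells had received ZsGreen alone (a fluorescent marker, the control), or ZsGreen together with ETV6 WT, ETV6 P214L or ETV6 I209S P214L. ETV6 is an ETS-family transcriptional repressor. Cells were sorted into medium without IL-3 on day 0 and harvested on day 3, with 3 libraries in each of the 4 groups. By the design, P214L creates a nuclear export sequence and I209S breaks it again, and the question was whether cells with I209S P214L resemble cells with ETV6 WT in their transcripts.

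The total counts of the 3 libraries were 17876563, 15156449 and 16866473 with ZsGreen, 16392565, 17347531 and 18607595 with ETV6 WT, 14767981, 17241881 and 15200735 with P214L, and 18268492, 14301683 and 16080807 with I209S P214L. Of 14794 genes tested, 6066 (41.0%) differed among the 4 groups. The first principal component held 40.8% of the variance and the second 14.2%. ZsGreen 1 stood apart from the other libraries on the second (70.7). ETV6 WT 1 (22.4) and I209S P214L 1 (21.2) came next on the same side, and the remaining libraries had values below 0. By correlation across genes, which are not independent replicates, 8 of the 12 libraries lay nearest to a library of another group: each ZsGreen library to a P214L library, ETV6 WT 1 and I209S P214L 1 to each other (r = 0.992), ETV6 WT 2 to I209S P214L 3, and I209S P214L 2 and I209S P214L 3 to ETV6 WT 2. 18S ribosomal RNA, a remnant after poly-A selection, took 3.85 ± 0.987% of counts with ZsGreen, 2.93 ± 1.17% with ETV6 WT, 4.89 ± 1.01% with P214L and 3.31 ± 1.74% with I209S P214L (SD, n = 3). Mitochondrially encoded RNA took 1.32 ± 0.0227%, 1.14 ± 0.142%, 1.21 ± 0.0306% and 1.2 ± 0.114% of counts in the same groups.

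Etv6 (ENSMUSG00000030199; chromosome 6, 134012663 to 134247121 on mm39) stood at 81.7 ± 5.03 CPM in ZsGreen cells, 109 ± 11.4 CPM with ETV6 WT, 103 ± 4.64 CPM with P214L and 99.1 ± 12 CPM with I209S P214L. It rose with ETV6 WT (log2 fold change 0.41, adjusted p = 0.00164), with P214L (0.34, adjusted p = 0.0433) and with I209S P214L (0.28, adjusted p = 0.0217). The rise with P214L was no longer called in 8 of the 12 fits with a library left out, namely without any ZsGreen or P214L library, without ETV6 WT 2 or without I209S P214L 3, and that with I209S P214L was not called without ZsGreen 2, ZsGreen 3, I209S P214L 1, or both ETV6 WT 1 and I209S P214L 1. Etv6 was not called different between I209S P214L and ETV6 WT (-0.13, adjusted p = 1). Counts per gene do not separate the construct from the cells' own Etv6. Nras stood at 77.9, 76.5, 80.9 and 77.3 CPM in the 4 groups and was not called in any comparison. Il3 had a count of 0 in all 12 libraries, which allows up to 0.0608 CPM in the ZsGreen group.

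**Figure D1:**
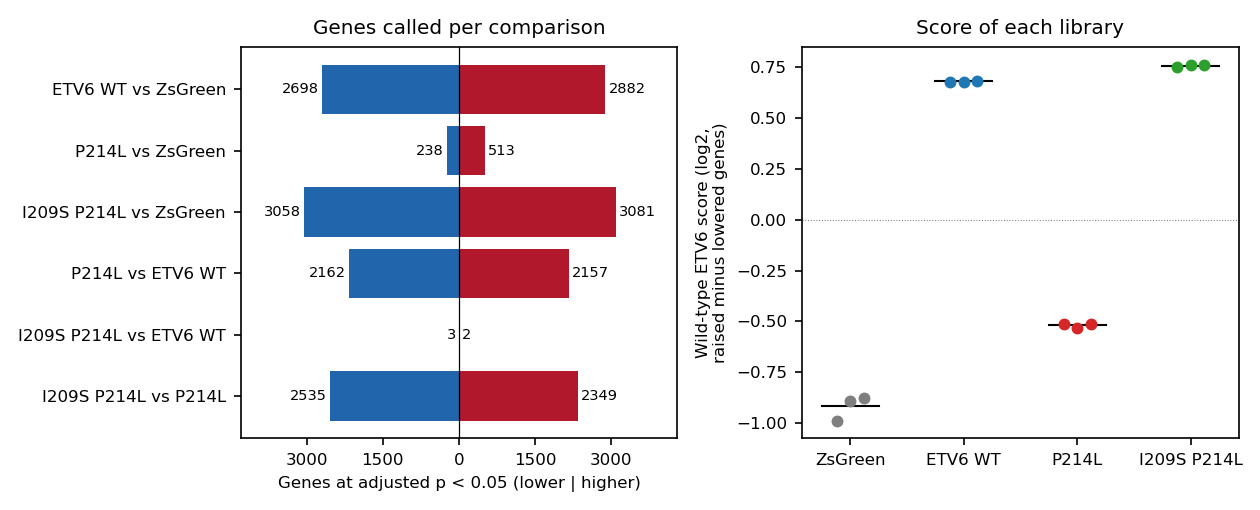
Left, genes higher (red) and lower (blue) at an adjusted p under 0.05 in each of the 6 comparisons, in number of genes. Right, the ETV6 WT score of each library (points, log2 units) with group means (lines); the 3 P214L libraries lie near -0.52, the 3 I209S P214L libraries near 0.76.

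ETV6 WT against ZsGreen asks what the repressor does to these cells. Angptl2, which encodes a secreted angiopoietin-like protein (ENSMUSG00000004105; chromosome 2, 33106081 to 33137729), rose from 4.97 ± 0.322 to 107 ± 4.07 CPM (n = 3 in each group), a 21.5-fold change (log2 fold change 4.42 ± 0.13 SE, adjusted p = 1.05e-13). Parvb, an adhesion adaptor, rose 19.5-fold, C3ar1, the receptor for complement C3a, rose 16.3-fold to 129 ± 1.37 CPM, and Aqp3, a glycerol and water channel, rose 15.8-fold. Fgf23, a hormone of phosphate balance (ENSMUSG00000000182; chromosome 6, 127049865 to 127058371), fell from 108.5 ± 7.81 to 0.837 ± 0.068 CPM, 129-fold (-7.01 ± 0.24, adjusted p = 7.32e-13). Alox5, the leukotriene-forming lipoxygenase, fell from 46.3 ± 4.52 to 2.91 ± 0.546 CPM (-4.00, adjusted p = 1.81e-11). Shank3, a scaffold protein, fell by 6.19 on the log2 scale and Ifitm6, an interferon-induced protein, fell by 4.22, and the stefins, which inhibit cysteine proteases, fell too, among them Cstdc5 (-6.53), Cstdc4 (-5.00) and Csta2 (-4.96). Other large rises were Slc37a2 (3.94), Gstm1 (3.30), Lilrb4a (3.11), Ahnak2 (3.05), Tmem171 (3.05) and Il34 (3.03), and other large falls were B4galnt4 (-3.91), Wdr66 (-3.89) and Csgalnact1 (-3.89). Stefin genes share reads with one another, so the share of each is uncertain.

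In all, 5580 genes changed with ETV6 WT (2882 higher, 2698 lower), 1194 of them at least 2-fold. The groups' libraries did not overlap for 6837 genes (46.2%), where chance gives 10%.

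Growth genes went down with ETV6 WT, and interferon and lysosome genes went up. Genes of MYC and ribosome biogenesis fell, with 25 lower of 25 and the same adjusted over the list alone. The ribosome biogenesis median was -0.75 (camera adjusted p = 3.58e-20, or 0.00233 with an estimated correlation). Nolc1, a nucleolar assembly factor, went from 261 to 132 CPM, and Odc1, the first enzyme of polyamine synthesis, from 246 to 118 CPM. Cell cycle genes fell, with 31 lower of 32 and the same adjusted over the list alone. The cell cycle median was -0.66 (camera adjusted p = 3.58e-20, or 0.0183 with an estimated correlation). The mitotic ubiquitin carrier Ube2c went from 222 to 106 CPM, the kinesin Kif11 from 276 to 155 CPM and Top2a from 1114 ± 24.4 to 694 ± 40.4 CPM. Cholesterol genes fell, with 16 lower and 1 higher of 24 and 18 lower and 1 higher adjusted over the list alone. The cholesterol median was -0.60 (camera adjusted p = 1.16e-08, or 0.0179 with an estimated correlation). Idi1 of sterol synthesis went from 34.6 to 9.37 CPM. Nuclear transport genes fell, with 11 lower of 17 and 12 lower adjusted over the list alone. The nuclear transport median was -0.39 (camera adjusted p = 3.31e-06, or 0.0179 with an estimated correlation). Ran, the transport GTPase, went from 709 to 404 CPM. Interferon genes rose, with 23 higher and 1 lower of 30 and 23 higher and 2 lower adjusted over the list alone. The interferon median was 0.83 (camera adjusted p = 6.72e-08, or 0.0179 with an estimated correlation). Irf7, which drives interferon transcription, went from 24.2 ± 3.60 to 64.5 ± 3.35 CPM. Lysosome genes rose, with 16 higher of 23 and 19 higher adjusted over the list alone. The lysosome median was 0.51 (camera adjusted p = 3.2e-12, or 0.0455 with an estimated correlation). The autophagy receptor Sqstm1 went from 228 ± 20.2 to 950.3 ± 61.3 CPM and the protease Ctsb from 150.4 to 337 CPM.

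For 7 more lists the call of camera rested on its preset correlation. Genes of the IL-3 receptor axis leaned higher, with 6 higher and 2 lower of 14 and the same adjusted over the list alone. The IL-3 axis median was 0.33 (camera adjusted p = 2.5e-05, or 0.0595 with an estimated correlation). Csf2rb, the beta chain shared by the IL-3, GM-CSF and IL-5 receptors, went from 343 ± 6.44 to 2027 ± 182 CPM (2.56). Its close copy Csf2rb2, specific to IL-3, went from 385 ± 13 to 2391 ± 119 CPM (2.64), and since these copies share reads, their split is uncertain. MHC class I genes leaned higher, with 7 higher and 2 lower of 15 and 8 higher and 2 lower adjusted over the list alone. The MHC class I median was 0.49 (camera adjusted p = 0.00316, or 0.218 with an estimated correlation). H2-T23 went from 129 to 318 CPM, though H2 genes share reads. Mast cell and basophil genes rose, with 6 higher and 3 lower of 12 and the same adjusted over the list alone. The mast cell median was 0.58 (camera adjusted p = 0.0172, or 0.0692 with an estimated correlation). The transcription factor Mitf led them (6.87 ± 2.11 to 34.6 ± 0.816 CPM). Neutrophil and monocyte genes fell, with 10 lower and 2 higher of 15 and the same adjusted over the list alone. The neutrophil median was -2.26 (camera adjusted p = 0.0011, or 0.0692 with an estimated correlation). S100a9 and S100a8, the subunits of calprotectin, fell 113-fold (counting interval 38.4 to 552) and 104-fold (28.5 to 868). Lysozyme Lyz2 fell by 3.53 on the log2 scale, and the macrophage receptor Adgre1 rose (2.68). Megakaryocyte genes fell, with 8 lower and 2 higher of 15 and 8 lower and 3 higher adjusted over the list alone. The megakaryocyte median was -0.27 (camera adjusted p = 0.0172, or 0.254 with an estimated correlation). Platelet factor Pf4 went from 22.3 ± 6.85 to 2.92 ± 0.225 CPM. Oxidative phosphorylation genes fell, with 19 lower and 1 higher of 28 and 21 lower and 1 higher adjusted over the list alone. The oxidative phosphorylation median was -0.30 (camera adjusted p = 0.000247, or 0.19 with an estimated correlation). Genes of the integrated stress response leaned lower, with 8 lower and 5 higher of 19 and 8 lower and 6 higher adjusted over the list alone. The stress response median was -0.21 (camera adjusted p = 0.00798, or 0.37 with an estimated correlation). Among the last, the serine enzyme Psat1 fell (294 to 114 CPM) and the cystine importer Slc7a11 rose (51.4 ± 6.24 to 159.6 ± 6.51 CPM).

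The other 12 tested lists were not called in ETV6 WT cells. ETS factors had 6 higher and 5 lower of 16, and 7 higher and 5 lower adjusted over the list alone. The ETS median was 0.08 (camera adjusted p = 0.79). Spi1, the myeloid factor PU.1, went from 148 to 254 CPM and Erg from 13.8 to 2.92 CPM. RAS-MAPK targets had 5 higher and 3 lower of 18, and the same adjusted over the list alone. The RAS-MAPK median was -0.03 and the mean 0.06, with camera leaning upward (camera adjusted p = 0.938). STAT5 targets had 7 lower and 4 higher of 17, and the same adjusted over the list alone. The STAT5 median was -0.07 (camera adjusted p = 0.0852). Apoptosis regulators had 7 lower and 5 higher of 21, and 8 lower and 6 higher adjusted over the list alone. The apoptosis median was 0.02 and the mean -0.33, with camera leaning downward (camera adjusted p = 0.79). The pro-apoptotic Bcl2l11 rose from 44.7 to 83.8 CPM, and its antagonist Bcl2l1 fell by 0.50 on the log2 scale. Targets of p53 had 7 lower and 3 higher of 20, and 8 lower and 4 higher adjusted over the list alone. The p53 median was -0.08 (camera adjusted p = 0.316). Glycolysis and hypoxia genes had 7 higher and 7 lower of 28, and the same adjusted over the list alone. The glycolysis median was -0.12 and the mean -0.03, with camera leaning upward (camera adjusted p = 0.718).

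Unfolded protein response genes had 9 lower and 3 higher of 19, and the same adjusted over the list alone. The unfolded protein median was -0.14 (camera adjusted p = 0.0734). NF-kB genes had 6 lower and 2 higher of 16, and the same adjusted over the list alone. The NF-kB median was -0.21 (camera adjusted p = 0.328). Erythroid genes had 6 higher and 4 lower of 14, and the same adjusted over the list alone. The erythroid median was 0.23 (camera adjusted p = 0.79). Stem and progenitor genes had 3 higher and 2 lower of 7, and the same adjusted over the list alone. The stem median was 0.20 and the mean -0.04, with camera leaning upward (camera adjusted p = 0.938). The progenitor factor Lmo2 went from 78.0 to 20.5 CPM. Mitochondrially encoded RNAs had 3 lower of 12, and the same adjusted over the list alone. The mitochondrial median was -0.17 (camera adjusted p = 0.172). Nuclear-retained RNAs had 1 higher and 2 lower of 6, and the same adjusted over the list alone. The nuclear RNA median was 0.08 (camera adjusted p = 0.516). Neat1, a scaffold of nuclear bodies, was the higher one (95.3 to 419 ± 56.4 CPM).

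**Figure D2:**
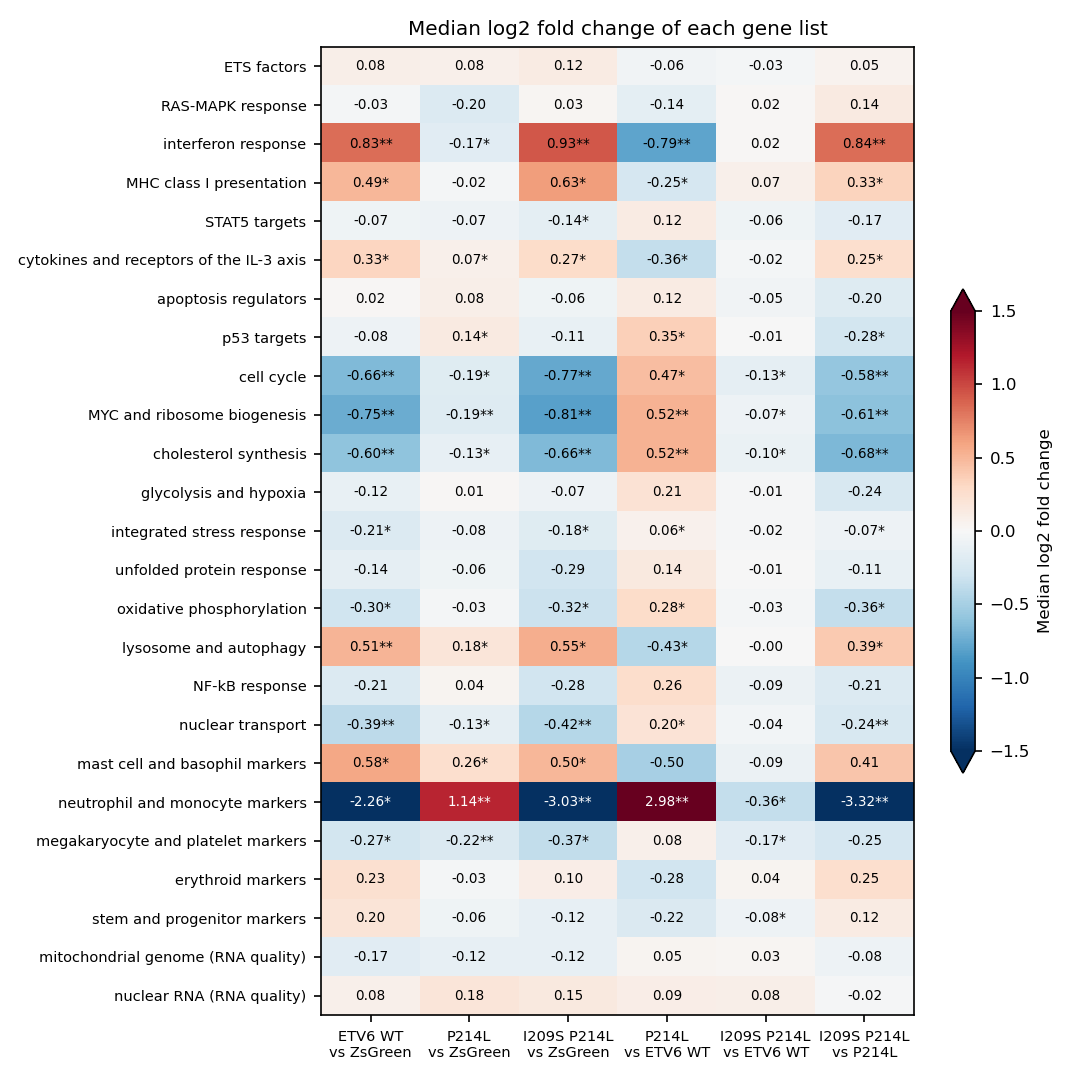
Median log2 fold change of the 25 tested gene lists (down) in the 6 comparisons (across), with colour from blue (lower) to red (higher) and limited at 1.5; 1 star marks camera with its preset correlation and 2 stars a call that held with an estimated correlation. In the column of I209S P214L against ETV6 WT no list carries 2 stars.

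P214L against ZsGreen asks what remains of ETV6's effect with the export sequence. Several genes of neutrophils and monocytes rose: S100a8 (ENSMUSG00000056054; chromosome 3, 90576285 to 90577342) went from 4.08 ± 1.02 to 22.5 ± 5.50 CPM, 5.51-fold (2.46 ± 0.29, adjusted p = 4.65e-05), its partner S100a9 from 6.60 ± 0.859 to 26.7 ± 6.33 CPM (2.01, adjusted p = 0.000105), and Lyz2 from 8.83 ± 2.89 to 36.1 ± 7.18 CPM (2.03, adjusted p = 0.000274). Cd33, a sialic acid receptor of myeloid cells, rose 5.52-fold (6.29 ± 1.21 to 34.7 ± 8.42 CPM), and Slc7a11 rose 1.82 on the log2 scale to 181 ± 22.6 CPM. The stefins Stfa2l1, Stfa1, Stfa3, Cstdc5 and Csta3 rose by 1.76 to 2.08. Of the platelet-lineage genes, Pf4 went from 22.3 ± 6.85 to 6.28 ± 0.185 CPM (-1.83, adjusted p = 5.19e-05) and Selp, the platelet selectin, changed by -1.19. Other falls were Rufy4 (-1.76), Sele (-1.47), Irag1 (-1.32), Alox5 (-0.96) and, less surely, Snx9 (-0.98, not called without ZsGreen 2, ZsGreen 3 or any P214L library) and C9orf72 (-0.95, not called by limma-voom or without P214L 3).

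In all, 751 genes changed with P214L (513 higher, 238 lower), 140 of them at least 2-fold, and the libraries did not overlap for 3797 genes (25.7%, with 10% by chance). The count rests on few libraries: it was 369, 489 and 390 without P214L 1, P214L 2 and P214L 3, 1152 with DESeq2, and 1224 without the first libraries of ETV6 WT and I209S P214L.

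Of the gene groups, 3 held with an estimated correlation. Neutrophil and monocyte genes rose, with 8 higher of 15 and 9 higher adjusted over the list alone. The neutrophil median was 1.14 (camera adjusted p = 4.89e-18, or 0.00354 with an estimated correlation). Megakaryocyte genes leaned lower, with 5 lower of 15 and 7 lower adjusted over the list alone. The megakaryocyte median was -0.22 (camera adjusted p = 2.46e-08, or 0.0406 with an estimated correlation). Genes of MYC and ribosome biogenesis leaned lower, with 5 lower of 25 and 14 lower adjusted over the list alone. The ribosome biogenesis median was -0.19 (camera adjusted p = 1.84e-09, or 0.0149 with an estimated correlation). Nolc1 was among the last (-0.35).

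In P214L cells the other 8 calls of lists rested on the preset correlation. Cell cycle genes leaned lower, with 7 lower of 32 and 12 lower adjusted over the list alone. The cell cycle median was -0.19 (camera adjusted p = 3.6e-11, or 0.0674 with an estimated correlation). The proliferation marker Mki67 went from 1062 to 857 CPM. Interferon genes leaned lower, with 5 lower of 30 and 9 lower adjusted over the list alone. The interferon median was -0.17 (camera adjusted p = 0.000364, or 0.0674 with an estimated correlation). Oasl2, an interferon-induced synthetase-like protein, went from 17.6 to 10.2 CPM. Lysosome genes leaned higher, with 7 higher of 23 and 12 higher adjusted over the list alone. The lysosome median was 0.18 (camera adjusted p = 2.87e-07, or 0.118 with an estimated correlation). The sialidase Neu1 was one of them (0.62). Nuclear transport genes leaned lower, with 1 lower of 17 and 5 lower adjusted over the list alone. The nuclear transport median was -0.13 (camera adjusted p = 0.000272, or 0.0535 with an estimated correlation). Cholesterol genes leaned lower, with 2 lower of 24 and 4 lower adjusted over the list alone. The cholesterol median was -0.13 (camera adjusted p = 0.0108, or 0.155 with an estimated correlation). Genes of the IL-3 receptor axis leaned higher, with 3 higher and 1 lower of 14 and 4 higher and 1 lower adjusted over the list alone. The IL-3 axis median was 0.07 (camera adjusted p = 0.007, or 0.155 with an estimated correlation). Without ZsGreen 1 that list was not called at the preset correlation either (adjusted p = 0.0821). Csf2rb went to 671 ± 43.2 CPM (0.97, adjusted p = 1.82e-07). Mast cell and basophil genes leaned higher, with 2 higher of 12 and the same adjusted over the list alone. The mast cell median was 0.26 (camera adjusted p = 0.00869, or 0.0674 with an estimated correlation). Targets of p53 leaned higher, with 4 higher of 20 and 8 higher and 1 lower adjusted over the list alone. The p53 median was 0.14 (camera adjusted p = 0.007, or 0.118 with an estimated correlation). The p53 antagonist Mdm2 was one of them (0.30).

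P214L against ETV6 WT asks where the mutant departs from the repressor. Lgmn, a lysosomal protease (ENSMUSG00000021190; chromosome 12, 102360343 to 102406072), stood at 88.9 ± 1.49 CPM with P214L and 817 ± 60.7 CPM with ETV6 WT (-3.20 ± 0.07, adjusted p = 3.59e-15). Angptl2 stood at 5.23 ± 1.5 against 107 ± 4.07 CPM (-4.37), C3ar1 at 14.1 against 129 CPM (-3.20), and Hba-a1, an alpha globin whose copies share reads, at 23.7 ± 11.7 against 235 ± 52.3 CPM (-3.30). Parvb (-4.59), Slc37a2 (-4.28), Aqp3 (-4.25), Tmem171 (-3.89), Ky (-3.60) and Il34 (-3.51) were lower too. Neutrophil genes were among the largest rises with P214L: S100a8 574-fold (counting interval 159 to 4.75e+03), S100a9 454-fold (155 to 2.21e+03), the collagenase Mmp8 824-fold (147 to 3.26e+04) and Lyz2 by 5.56 on the log2 scale. The stefin Stfa2l1, without a count in ETV6 WT cells, was at least 484-fold higher, Csta3 was 435-fold higher (120 to 3.60e+03), and Cstdc5, Stfa3, Stfa2, Stfa1 and Cstdc4 were higher by 6.63 to 8.55.

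In all, 4319 genes differed between P214L and ETV6 WT (2157 higher, 2162 lower), 755 of them at least 2-fold, and the libraries did not overlap for 6710 genes (45.4%, with 10% by chance). Xpo1, the export receptor, stood at 255 ± 4.63 CPM in ZsGreen cells, 166 ± 9.75 CPM with ETV6 WT (-0.62, adjusted p = 2.99e-07), 225 ± 4.06 CPM with P214L (-0.18, adjusted p = 0.105) and 159 ± 3.98 CPM with I209S P214L (-0.68, adjusted p = 8.05e-08), and was higher with P214L than with ETV6 WT (0.44, adjusted p = 2.55e-05).

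Interferon genes were lower with P214L, with 23 lower of 30 and the same adjusted over the list alone. The interferon median was -0.79 (camera adjusted p = 4.02e-16, or 0.00404 with an estimated correlation). Against ETV6 WT, Irf7 changed by -1.70 and Oasl2 by -2.27. Genes of MYC and ribosome biogenesis were higher with P214L, with 23 higher of 25 and 24 higher adjusted over the list alone. The ribosome biogenesis median was 0.52 (camera adjusted p = 9.09e-14, or 0.00404 with an estimated correlation). Cholesterol genes were higher with P214L, with 17 higher of 24 and 18 higher adjusted over the list alone. The cholesterol median was 0.52 (camera adjusted p = 1.1e-07, or 0.0224 with an estimated correlation). Idi1 was higher by 1.40. Neutrophil and monocyte genes were higher with P214L, with 11 higher and 2 lower of 15 and the same adjusted over the list alone. The neutrophil median was 2.98 (camera adjusted p = 1.68e-13, or 0.00404 with an estimated correlation). These 4 lists held with an estimated correlation.

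The rest of the 12 list calls between P214L and ETV6 WT rested on the preset correlation. Cell cycle genes were higher with P214L, with 29 higher of 32 and the same adjusted over the list alone. The cell cycle median was 0.47 (camera adjusted p = 7.64e-13, or 0.0562 with an estimated correlation). The mitotic kinase Cdk1 stood at 106 against 64.9 CPM. Nuclear transport genes leaned higher with P214L, with 8 higher of 17 and 11 higher adjusted over the list alone. The nuclear transport median was 0.20 (camera adjusted p = 0.000566, or 0.0562 with an estimated correlation). Oxidative phosphorylation genes were higher with P214L, with 18 higher and 1 lower of 28 and the same adjusted over the list alone. The oxidative phosphorylation median was 0.28 (camera adjusted p = 0.000262, or 0.176 with an estimated correlation). Targets of p53 were higher with P214L, with 10 higher and 2 lower of 20 and 11 higher and 2 lower adjusted over the list alone. The p53 median was 0.35 (camera adjusted p = 0.00565, or 0.111 with an estimated correlation). Genes of the integrated stress response leaned higher with P214L, with 7 higher and 2 lower of 19 and the same adjusted over the list alone. The stress response median was 0.06 (camera adjusted p = 0.00547, or 0.346 with an estimated correlation). Lysosome genes were lower with P214L, with 13 lower and 1 higher of 23 and 14 lower and 1 higher adjusted over the list alone. The lysosome median was -0.43 (camera adjusted p = 6.74e-08, or 0.105 with an estimated correlation). Sqstm1 stood at 298 against 950.3 CPM. MHC class I genes were lower with P214L, with 8 lower of 15 and the same adjusted over the list alone. The MHC class I median was -0.25 (camera adjusted p = 0.000139, or 0.111 with an estimated correlation). Genes of the IL-3 receptor axis leaned lower with P214L, with 6 lower and 2 higher of 14 and 7 lower and 2 higher adjusted over the list alone. The IL-3 axis median was -0.36 (camera adjusted p = 0.000262, or 0.105 with an estimated correlation). Csf2rb2 stood at 668 against 2391 ± 119 CPM.

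I209S P214L against ETV6 WT asks whether the second mutation brings the repressor's transcripts back. Wnt10b, a Wnt ligand (ENSMUSG00000022996; chromosome 15, 98668593 to 98676031), stood at 19.2 ± 1.14 CPM with I209S P214L and 6.30 ± 0.622 CPM with ETV6 WT (1.61 ± 0.25, adjusted p = 0.0216), and Angptl2 at 176 ± 10.8 against 107 ± 4.07 CPM (0.72 ± 0.10, adjusted p = 0.0141). Ms4a3, a membrane protein of granulocyte and monocyte precursors (ENSMUSG00000024681; chromosome 19, 11606860 to 11618215), stood at 33.3 ± 4.52 against 51.7 ± 1.15 CPM (-0.63 ± 0.09, adjusted p = 0.0141). The noncoding RNA F630028O10Rik (ENSMUSG00000078122; chromosome X, 95283498 to 95287267), named after its values were seen, was lower as well (-0.48, adjusted p = 0.0450). These are 4 of the 5 genes that edgeR called (2 higher, 3 lower), and 512 (3.46%) had an unadjusted p under 0.05.

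Each of these 4 calls ended under some alternatives. Wnt10b was not called without any 1 of the 6 compared libraries, with adjusted p from 0.0771 to 0.258, nor without the first libraries of both groups (0.170). Angptl2 and Ms4a3 were not called without ETV6 WT 2, ETV6 WT 3, I209S P214L 2 or I209S P214L 3, in each of which fits 1 gene was called, with adjusted p up to 0.158 for Angptl2. Ms4a3 was not called by limma-voom (adjusted p = 0.0709) or in a fit of the compared groups alone (0.400) either. F630028O10Rik lost its call in 18 of 24 alternatives, among them RLE and total count scaling, the replicate block, and the fits without ZsGreen 2, ZsGreen 3, any P214L or I209S P214L library, ETV6 WT 2 or ETV6 WT 3 (adjusted p up to 0.554).

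DESeq2 called 23 genes between I209S P214L and ETV6 WT, limma-voom 3, a fit without a filter 38, and a fit of the compared groups alone 3. The 95% interval of the difference lay within 1.5-fold for 8889 genes (60.1%) and within 2-fold for 10512 (71.1%), so differences of those sizes remain open for the rest. The libraries did not overlap for 1233 genes (8.33%), where chance gives 10%.

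No member of any gene list was called between I209S P214L and ETV6 WT over all genes by edgeR. At its preset correlation camera called 6 lists lower with I209S P214L, and 0 of them held with an estimated correlation or with fry. Cell cycle genes leaned lower, with 0 lower of 32 and the same adjusted over the list alone. The cell cycle median was -0.13 (camera adjusted p = 8.91e-08, or 0.161 with an estimated correlation). Genes of MYC and ribosome biogenesis leaned lower, with 0 lower of 25 and the same adjusted over the list alone. The ribosome biogenesis median was -0.07 (camera adjusted p = 0.000466, or 0.12 with an estimated correlation). Cholesterol genes leaned lower, with 0 lower of 24 and the same adjusted over the list alone. The cholesterol median was -0.10 (camera adjusted p = 0.00188, or 0.153 with an estimated correlation). Without ETV6 WT 1 it was not called at the preset correlation either (adjusted p = 0.0567). Neutrophil and monocyte genes leaned lower, with 0 lower of 15 and 1 lower adjusted over the list alone. The neutrophil median was -0.36 (camera adjusted p = 0.000784, or 0.12 with an estimated correlation). Megakaryocyte genes leaned lower, with 0 lower of 15 and 5 lower adjusted over the list alone. The megakaryocyte median was -0.17 (camera adjusted p = 6.58e-07, or 0.12 with an estimated correlation). Stem and progenitor genes leaned lower, with 0 lower of 7 and 2 lower adjusted over the list alone. The stem median was -0.08 (camera adjusted p = 0.00282, or 0.121 with an estimated correlation).

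**Figure D3:**
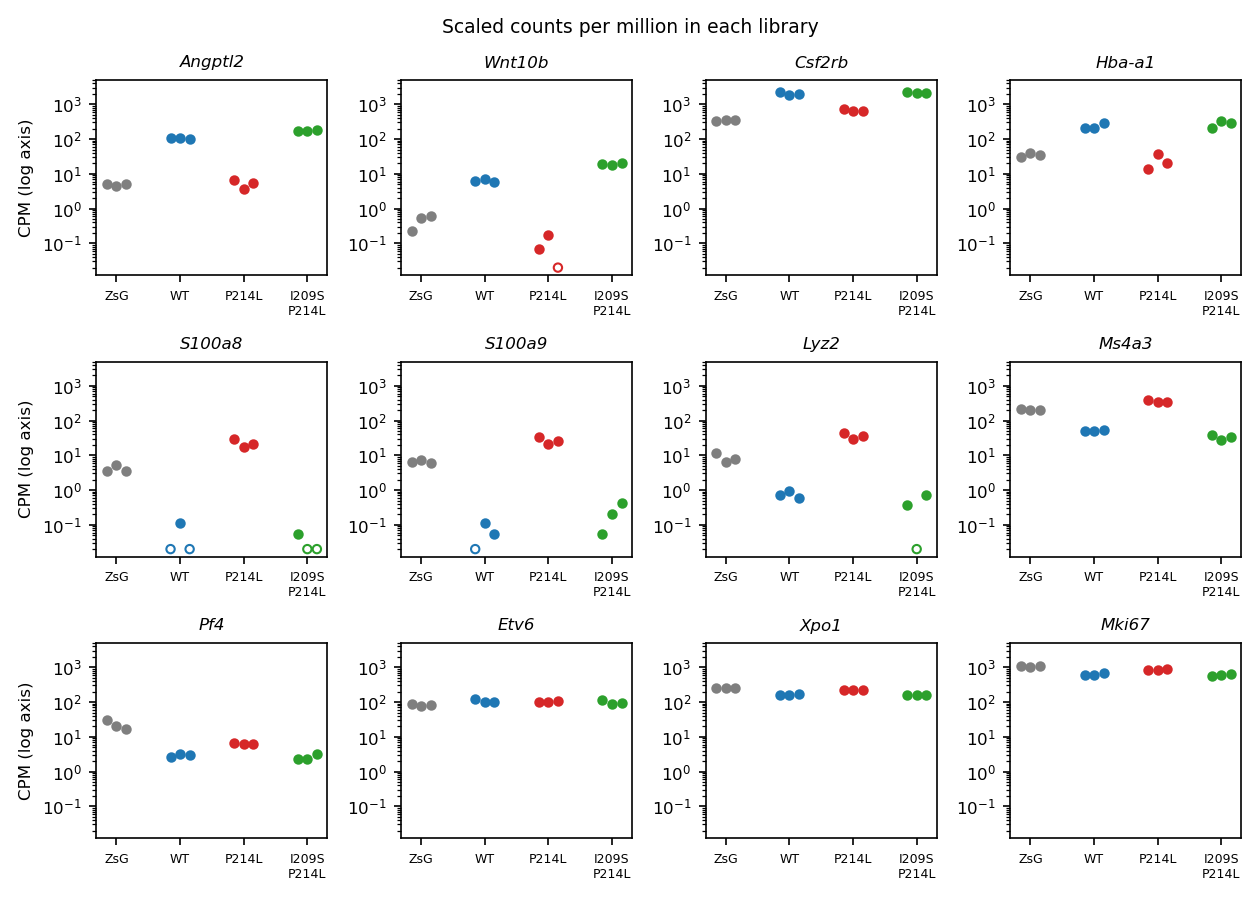
Level of 12 genes in each library (points, scaled CPM on a log axis) in the 4 groups, with open circles at the bottom for a count of 0. For Angptl2, Csf2rb and Hba-a1 the ETV6 WT and I209S P214L libraries lie together above the other two groups, and for S100a8, S100a9 and Lyz2 they lie below.

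I209S P214L against P214L asks what breaking the export sequence alone changes. Angptl2 rose from 5.23 ± 1.5 to 176 ± 10.8 CPM, 33.9-fold (5.08), Wnt10b rose by 7.69 on the log2 scale, and Ngef, a guanine nucleotide exchange factor, and the embryonic globin Hba-x, both without a count in P214L cells, rose at least 187-fold and at least 190-fold. Hbb-bs, an adult beta globin, changed by 7.06. Neutrophil genes were among the largest falls, S100a8 by 1.07e+03-fold (counting interval 191 to 4.22e+04), Mmp8 by 766-fold (137 to 3.03e+04), as did Lyz2 (-6.53) and S100a9 (-6.84), and the stefins Csta3 (at least 270-fold lower), Stfa1 (1196-fold, 214.3 to 47296) and Stfa2 (759-fold, 136 to 3.00e+04) fell with them. Csf2rb rose by 1.68. In all, 4884 genes changed (2349 higher, 2535 lower), 966 of them at least 2-fold, and the libraries did not overlap for 7126 genes (48.2%, with 10% by chance).

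Interferon genes rose, with 23 higher of 30 and 24 higher adjusted over the list alone. The interferon median was 0.84 (camera adjusted p = 6.5e-15, or 0.00296 with an estimated correlation). Oasl2 (2.21) and Irf7 (1.73) led them between P214L and I209S P214L. Genes of MYC and ribosome biogenesis fell, with 25 lower of 25 and the same adjusted over the list alone. The ribosome biogenesis median was -0.61 (camera adjusted p = 3.71e-15, or 0.00292 with an estimated correlation). Cell cycle genes fell, with 30 lower of 32 and 31 lower adjusted over the list alone. The cell cycle median was -0.58 (camera adjusted p = 2.18e-15, or 0.0406 with an estimated correlation). Cholesterol genes fell, with 19 lower and 1 higher of 24 and the same adjusted over the list alone. The cholesterol median was -0.68 (camera adjusted p = 1.03e-08, or 0.0106 with an estimated correlation). Nuclear transport genes fell, with 11 lower of 17 and the same adjusted over the list alone. The nuclear transport median was -0.24 (camera adjusted p = 0.000344, or 0.0428 with an estimated correlation). Neutrophil and monocyte genes fell, with 12 lower and 2 higher of 15 and the same adjusted over the list alone. The neutrophil median was -3.32 (camera adjusted p = 7.44e-14, or 0.00292 with an estimated correlation). These 6 lists held with an estimated correlation.

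From P214L to I209S P214L a further 6 lists were called at the preset correlation alone. Lysosome genes rose, with 13 higher and 1 lower of 23 and 14 higher and 2 lower adjusted over the list alone. The lysosome median was 0.39 (camera adjusted p = 2.12e-07, or 0.119 with an estimated correlation). MHC class I genes rose, with 9 higher of 15 and the same adjusted over the list alone. The MHC class I median was 0.33 (camera adjusted p = 6.51e-05, or 0.119 with an estimated correlation). Genes of the IL-3 receptor axis leaned higher, with 5 higher and 2 lower of 14 and 5 higher and 3 lower adjusted over the list alone. The IL-3 axis median was 0.25 (camera adjusted p = 0.00202, or 0.164 with an estimated correlation). Oxidative phosphorylation genes fell, with 18 lower and 1 higher of 28 and 20 lower and 1 higher adjusted over the list alone. The oxidative phosphorylation median was -0.36 (camera adjusted p = 0.000394, or 0.195 with an estimated correlation). Targets of p53 leaned lower, with 9 lower and 3 higher of 20 and 11 lower and 3 higher adjusted over the list alone. The p53 median was -0.28 (camera adjusted p = 0.0315, or 0.195 with an estimated correlation). Genes of the integrated stress response leaned lower, with 7 lower and 2 higher of 19 and the same adjusted over the list alone. The stress response median was -0.07 (camera adjusted p = 0.0199, or 0.399 with an estimated correlation).

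I209S P214L against ZsGreen gave the whole effect of the mutant with both changes. Angptl2 rose 35.2-fold (4.97 ± 0.322 to 176 ± 10.8 CPM), Csf2rb2 went to 2504 ± 32.4 CPM (2.70), Sqstm1 to 1145 ± 87.8 CPM (2.33), Irf7 to 65.9 CPM (1.45) and Hba-a1 to 275 ± 67.8 CPM (2.97), while Fgf23 fell from 108.5 ± 7.81 to 0.629 CPM (-7.37) and Shank3 by 7.71 on the log2 scale. Ngef and Hba-x, without a count in ZsGreen cells, rose at least 198-fold and at least 201-fold, Wnt10b changed by 5.40, Hbb-bs by 5.61, and the stefins Cstdc4, Cstdc5 and Csta2 fell by 6.57, by 5.77 and by 5.36 on that scale. In all, 6139 genes changed (3081 higher, 3058 lower), 1485 of them at least 2-fold, and the libraries did not overlap for 7069 genes (47.8%, with 10% by chance).

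Against ZsGreen, 14 lists were called with I209S P214L, and 6 held with an estimated correlation. Genes of MYC and ribosome biogenesis fell, with 25 lower of 25 and the same adjusted over the list alone. The ribosome biogenesis median was -0.81 (camera adjusted p = 3.91e-21, or 0.0016 with an estimated correlation). Cell cycle genes fell, with 31 lower of 32 and the same adjusted over the list alone. The cell cycle median was -0.77 (camera adjusted p = 1.43e-22, or 0.0173 with an estimated correlation). Cholesterol genes fell, with 18 lower and 1 higher of 24 and the same adjusted over the list alone. The cholesterol median was -0.66 (camera adjusted p = 1.44e-09, or 0.0137 with an estimated correlation). Nuclear transport genes fell, with 12 lower of 17 and the same adjusted over the list alone. The nuclear transport median was -0.42 (camera adjusted p = 2.37e-06, or 0.0173 with an estimated correlation). Neutrophil and monocyte genes fell, with 11 lower and 2 higher of 15 and the same adjusted over the list alone. The neutrophil median was -3.03 (camera adjusted p = 0.00025, or 0.0303 with an estimated correlation). Interferon genes rose, with 23 higher and 1 lower of 30 and 24 higher and 2 lower adjusted over the list alone. The interferon median was 0.93 (camera adjusted p = 2.07e-07, or 0.0173 with an estimated correlation).

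The other 8 lists with I209S P214L rested on the preset correlation. Lysosome genes rose, with 18 higher of 23 and the same adjusted over the list alone. The lysosome median was 0.55 (camera adjusted p = 3.13e-11, or 0.05 with an estimated correlation). MHC class I genes rose, with 8 higher and 3 lower of 15 and the same adjusted over the list alone. The MHC class I median was 0.63 (camera adjusted p = 0.00134, or 0.171 with an estimated correlation). Genes of the IL-3 receptor axis leaned higher, with 4 higher and 2 lower of 14 and the same adjusted over the list alone. The IL-3 axis median was 0.27 (camera adjusted p = 0.00025, or 0.0897 with an estimated correlation). Mast cell and basophil genes rose, with 6 higher and 2 lower of 12 and the same adjusted over the list alone. The mast cell median was 0.50 (camera adjusted p = 0.0456, or 0.123 with an estimated correlation). With the replicate block that list was not called (adjusted p = 0.0541). Megakaryocyte genes fell, with 9 lower of 15 and 9 lower and 1 higher adjusted over the list alone. The megakaryocyte median was -0.37 (camera adjusted p = 0.000863, or 0.13 with an estimated correlation). Oxidative phosphorylation genes fell, with 18 lower and 1 higher of 28 and 19 lower and 1 higher adjusted over the list alone. The oxidative phosphorylation median was -0.32 (camera adjusted p = 0.000339, or 0.171 with an estimated correlation). STAT5 targets leaned lower, with 7 lower and 4 higher of 17 and the same adjusted over the list alone. The STAT5 median was -0.14 (camera adjusted p = 0.0464, or 0.336 with an estimated correlation). This call ended with the replicate block (adjusted p = 0.0541) and without ZsGreen 2 (0.0598), ZsGreen 3 (0.0607), I209S P214L 2 (0.0756) or I209S P214L 3 (0.0604). Genes of the integrated stress response leaned lower, with 8 lower and 6 higher of 19 and 9 lower and 7 higher adjusted over the list alone. The stress response median was -0.18 (camera adjusted p = 0.0216, or 0.415 with an estimated correlation).

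The 5580 genes of ETV6 WT were then followed across the mutants. The 2882 genes it raised had a median log2 fold change of 0.63 with ETV6 WT, 0.16 with P214L and 0.64 with I209S P214L against ZsGreen, and the 2698 genes it lowered had medians of -0.54, -0.14 and -0.57. From P214L to I209S P214L, 5394 of them (96.7%) moved in the direction of ETV6 WT, 3881 as called changes and 24 as called changes the other way, and 5 differed between I209S P214L and ETV6 WT. The least-squares slope of that change on the change from ZsGreen to ETV6 WT, which share no library, was 0.737 over all of them, 0.599 over the raised and 1.01 over the lowered genes. It was 0.934 when genes were kept by a mean CPM of at least 5, and 0.487 without ZsGreen 2. The medians with P214L (0.16 and -0.14) lay part of the way from ZsGreen to ETV6 WT. These genes were chosen against the same ZsGreen libraries, so chance deviations of the controls may make part or all of this. If P214L keeps part of the effect, a slope below 1 need not mean that I209S P214L fell short of ETV6 WT. The medians with P214L were similar shares of those with ETV6 WT in both directions (0.16 of 0.63 and -0.14 of -0.54). They therefore do not account for the unlike slopes of 0.599 and 1.01. Of the 4319 genes that told P214L from ETV6 WT, 3920 (90.8%) moved back as called changes between P214L and I209S P214L, and 4 of the 4319 differed between I209S P214L and ETV6 WT. The choice of these genes and their move back share the P214L libraries. A chance deviation of P214L would therefore count as a move back, and how much of the 90.8% it makes is not known.

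**Figure D4:**
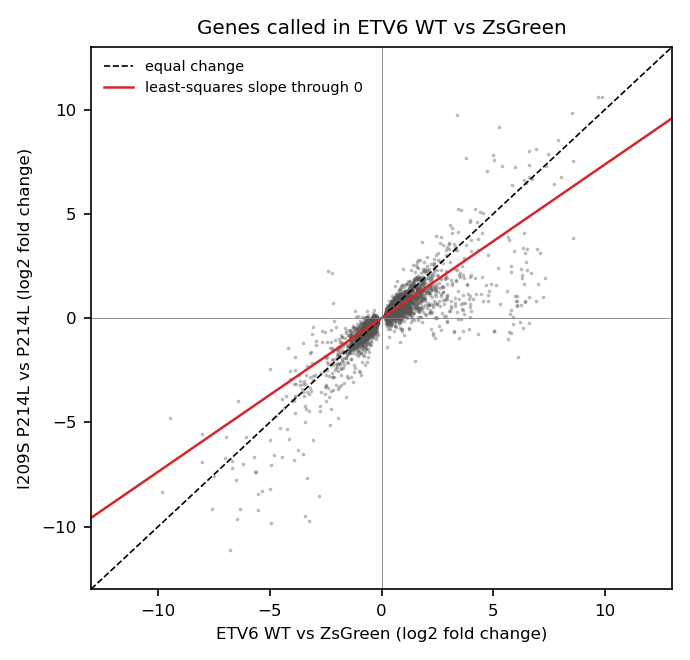
Log2 fold change from ZsGreen to ETV6 WT (horizontal) and from P214L to I209S P214L (vertical) for the 5580 genes called with ETV6 WT (points), with a dashed line of equal change and a red line of the least-squares slope. The red line has a slope of 0.737.

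The ETV6 WT score was -0.92 ± 0.06 with ZsGreen, -0.52 ± 0.01 with P214L, 0.68 ± 0.003 with ETV6 WT and 0.76 ± 0.006 with I209S P214L (SD, n = 3; log2 units). P214L exceeded ZsGreen by 0.40, I209S P214L exceeded P214L by 1.28 and ETV6 WT by 0.08, and in each of these pairs the libraries did not overlap. The two-sided exact permutation p was 0.1 for each pair, the smallest that 3 against 3 libraries allow. The score's genes were chosen on the ETV6 WT and ZsGreen libraries, so those groups are not independent of it.

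Comparisons against the same ZsGreen libraries share their chance values, and the expected numbers are those of independent lists, which leave the shared control out. Of genes called with both ETV6 WT and P214L against ZsGreen, 546 moved the same way (370 higher, 176 lower; 143 expected) and 82 in opposite ways (139.9 expected). With ETV6 WT and I209S P214L 5134 moved the same way (1158 expected) and 1 the other way. With P214L and I209S P214L 538 moved the same way (156 expected) and 95 in opposite ways. In simulations with the shared control and no effect, 0 genes were called in both comparisons of any pair. The log2 fold changes of ETV6 WT and P214L correlated at r = 0.506 over all tested genes, against 0.5002 simulated with no effect. For P214L and I209S P214L r was 0.488 (0.5004 simulated), and for ETV6 WT and I209S P214L 0.926 (0.5023 simulated). The covariances were 0.310, 0.321 and 0.933 in the same order, and exceeded the simulated ones by 0.230, 0.240 and 0.853. With 3 control libraries, which cannot be divided, the part of the shared control in these numbers is not known.

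The deposited tests of the authors gave 4863, 1274 and 5275 genes against ZsGreen for ETV6 WT, P214L and I209S P214L, 4606 for P214L against ETV6 WT, 15 for I209S P214L against ETV6 WT and 5104 for I209S P214L against P214L. No gene called in both the deposited tests and the edgeR fit had opposite directions in any of these comparisons, and 5 of the deposited 15 were the genes called here.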

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

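All tests of explanations and of other splits in this part were chosen after the results they concern had been seen.

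Calprotectin and its neighbours moved in opposite ways in cells with ETV6 WT and cells with P214L: S100a8 and S100a9 fell with the former and rose with the latter (2.46 and 2.01 on the log2 scale). In all, 82 genes were called in opposite directions by ETV6 WT and P214L against the same ZsGreen libraries. All 82 also differed between ETV6 WT and P214L themselves, which nearly follows from opposite calls in the same fit and is no further support. Of the 82, 60 were lowered by ETV6 WT and raised by P214L, and 22 went the other way, among them Oasl2 (1.48 with ETV6 WT, -0.79 with P214L), Lat, an adaptor of T-cell signalling (2.02 and -0.67), and Ndrg1, a gene of the hypoxia response (1.12 and -0.60). Between I209S P214L and P214L the corresponding number was 95.

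Several explanations of the 82 genes were set against the tables. ZsGreen 1, which stood apart from the other control libraries, is not needed for the pattern, since 65 genes were called in opposite ways without it. The number was 52 without P214L 1 and 53 without P214L 3. Reads shared between stefin copies concern 8 of the 82. That P214L opposes ETV6 WT across its genes at large is argued against by the positive excess covariance of 0.230, although part of that excess may come from the shared control. Of the 15 tested members of the neutrophil and monocyte list, 5 (Cd14, Lyz2, Ngp, S100a8 and S100a9) are among the 60 genes. No biological explanation was tested, and the source of the pattern stays open.

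ETV6 WT 1 and I209S P214L 1 departed from their groups in the same way, with a correlation of 0.528 between their deviations across genes, which are not independent replicates. A swap of their labels would turn the genes that separate the groups without them. Of 7 such genes 4 had the same sign between these libraries, and 3 of the Rpl17 family, whose copies share reads, had the opposite sign. These signs alone do not decide. The ETV6 WT score argues against a swap, though ETV6 WT 1 was among the libraries that chose its genes. ETV6 WT 1 scored 0.680, with 0.679 and 0.685 in ETV6 WT 2 and ETV6 WT 3. I209S P214L 1 scored 0.752, with 0.763 and 0.760 in I209S P214L 2 and I209S P214L 3. The opposite signs of the Rpl17 family remain unexplained. For ribosomal RNA acting through the scaling, the correlation was taken over protein-coding genes scaled among themselves, and was 0.369. A scaling factor shifts all genes of a library alike and leaves such a correlation nearly unchanged, so this value cannot decide. It shows only that the likeness was present among protein-coding genes alone. A batch of all 4 first libraries is argued against, as the lowest correlation among their deviations was -0.0610, between ETV6 WT 1 and P214L 1. The deviations of ZsGreen 1 correlated at 0.0900 with those of ETV6 WT 1 and at 0.0963 with those of I209S P214L 1. A batch of first libraries without P214L 1 was not tested. These libraries also held the least 18S ribosomal RNA (1.58% of counts in ETV6 WT 1 and 1.35% in I209S P214L 1, at least 2.92% elsewhere) and the largest shares of protein-coding genes (at most 93.1% elsewhere). Malat1, a nuclear-retained RNA, stood at 781 and 763 CPM in them, against 2608 and 2767 CPM in the other ETV6 WT libraries and 3698 and 3520 CPM in the other I209S P214L libraries. Handling or RNA quality shared by these libraries alone cannot be told apart from a biological likeness of their cultures by these values, because the labels give neither.

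The I209S P214L libraries scored beyond those of ETV6 WT by 0.0770 on average. The choice of the score's genes on ETV6 WT and ZsGreen libraries would favour ETV6 WT and so cannot have made this difference of 0.0770. Neither did the first libraries make it, since the lowest I209S P214L score still exceeded the highest ETV6 WT score by 0.0755 among libraries 2 and 3. A larger amount of construct in I209S P214L cells may be the source and cannot be told apart from a stronger protein, because Etv6 counts (-0.13) do not separate the construct from the endogenous gene. The exact permutation p of 0.1 is the smallest that 3 against 3 libraries allow, whatever the data, so it speaks neither for nor against the difference in score.

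Regrouping the 6 libraries of each pair gives 10 splits, too few for a share under 0.05, so only the values are given. For ETV6 WT against ZsGreen the real split called 5580 genes, the only 1 of 10 with as many, and the highest of the others called 0. For P214L against ZsGreen the real split called 751 and the highest other 1, again 1 of 10. For I209S P214L against ZsGreen (6139 genes), P214L against ETV6 WT (4319) and I209S P214L against P214L (4884) the highest other split called 0, and 1 of 10 gave as many. For I209S P214L against ETV6 WT 2 of 10 splits gave at least the 5 genes, and the highest other called 339: it set ETV6 WT 1, ETV6 WT 2 and I209S P214L 1 against the rest, which points to a structure of these libraries that the groups do not follow. For the test across the 4 groups, 1 of 100 splits, the real one itself, gave as many genes as the real 6066, the highest of the others being 877. This argues against a chance division of the 12 libraries. It cannot exclude chance differences between cultures, since the 3 libraries of a group may be technical replicates.

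For the gene lists at camera's preset correlation the other splits came close. ETV6 WT against ZsGreen gave 13 lists and the highest other split 10, P214L against ZsGreen 11 and 8, I209S P214L against ZsGreen 14 and 8, and I209S P214L against P214L 12 and 10, with 1 of 10 splits as high in each. P214L against ETV6 WT gave 12 lists, 4 of 10 splits gave as many and the highest 13. I209S P214L against ETV6 WT gave 6, 2 of 10 gave as many and the highest 8. These splits too are too few for a share under 0.05.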

How the results depend on the processing

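The alternatives that left out first libraries, removed ribosomal RNA genes or restricted the slope to genes above the floor were chosen after seeing the data; the others were planned.

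Of 18693 values of named genes under the alternatives 18396 kept their direction and their side of the threshold, 182 lost the call, 115 gained one and 0 turned round; 132 had no adjusted p with DESeq2. The alternatives that lost the largest numbers of calls were those without P214L 1 (28), P214L 2 (21) or P214L 3 (20). With a block for replicate number 1 of 553 calls was lost, that of F630028O10Rik between I209S P214L and ETV6 WT. The numbers did not pair the libraries across all groups, since 2 of 18 pairs of groups and numbers had deviations correlated above 0.1. Both lay between ETV6 WT and I209S P214L (0.528 for libraries 1, 0.254 for libraries 3, and 0.0786 for libraries 2). There ETV6 WT 3 and I209S P214L 2, of unlike number, correlated too (0.161), so pairing of these groups stays open. No scaling moved the median of all genes by more than 0.1.

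The counts of ETV6 WT against ZsGreen, I209S P214L against ZsGreen, P214L against ETV6 WT and I209S P214L against P214L stayed within 1.5 times under every alternative run. For P214L against ZsGreen (751) the count was 1152 with DESeq2, 1224 without the first libraries of ETV6 WT and I209S P214L, and 369 to 960 with each library left out. For I209S P214L against ETV6 WT (5) it was 23 with DESeq2, 3 with limma-voom, 38 without a filter, 3 with only the 2 groups, 8 without the first libraries of ZsGreen, ETV6 WT and I209S P214L, and 1 to 6 with each library left out (1 without ETV6 WT 2, ETV6 WT 3, I209S P214L 2 or I209S P214L 3). The cause was not tested.

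Genes called the same way with ETV6 WT and P214L (546) numbered 862 with DESeq2, 897 without the first libraries of ETV6 WT and I209S P214L, 69 at 2-fold or more, and 265 to 698 with each library left out. Genes called in opposite ways (82) numbered 26 at 2-fold or more and 52 to 96 with each library left out. With ETV6 WT and I209S P214L, 1064 moved the same way at 2-fold or more; the 1 opposite gene became 0 with protein-coding genes alone and at 2-fold or more, 2 without the first libraries, and 0 to 1 with each library left out. With P214L and I209S P214L the same-way count (538) was 855 with DESeq2, 881 without the first libraries, 67 at 2-fold or more and 258 to 707 with each library left out; the opposite count (95) was 27 at 2-fold or more and 57 to 111. Fewer genes pass a 2-fold bound by construction, and for the rest the cause was not tested. limma-voom divided the same-way genes of ETV6 WT and P214L into 337 higher and 250 lower, against 370 and 176.

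With an estimated correlation camera called 6 lists for ETV6 WT against ZsGreen, 3 for P214L against ZsGreen, 6 for I209S P214L against ZsGreen, 4 for P214L against ETV6 WT, 0 for I209S P214L against ETV6 WT and 6 for I209S P214L against P214L. fry, which asks another question, called 0 for I209S P214L against ETV6 WT and 19 for I209S P214L against P214L. The difference in score between I209S P214L and P214L was 3.18 over genes changed at least 2-fold, which are larger changes by construction, and 1.35 with a prior count of 0.5. The slope ran from 0.487 (without ZsGreen 2) to 0.695 with each library left out, all below 0.737, with a jackknife error of 0.214, and the cause was not tested; over 5431 genes above the floor in every group it was 0.8001.

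Depth limits the genes of few counts: folds against groups with 0 to 3 counts are bounds or wide intervals, and planted 1.5-fold changes were recovered in 50% to 60% of cases.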

Other observations

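The tests named in this part were planned, except where a value is said to have been looked up afterwards.

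Markers of the B lineage were sparse in this pro-B line. Rag1 and Il7r had a count of 0 in all 12 libraries, which allows up to 0.0643 CPM in the P214L group and less in the others. Cd79a, part of the B-cell receptor, stood at 1.48 ± 1.18 CPM with ZsGreen and 1.34 ± 0.329 CPM with ETV6 WT (n = 3), and was not called. Of 4 B-lineage genes with enough counts 1 changed with ETV6 WT, Cd72, which rose from 5.70 to 9.84 CPM (0.79). Of 3 T-lineage genes, Lat (18.1 to 73.1 CPM) and the transcription factor Tcf7 (3.79 on the log2 scale) rose with ETV6 WT, and of 3 fibroblast genes the collagen Col5a1 rose (346 to 777 CPM) and the actin Acta2 fell (-2.03). The counts adjusted over the list alone were the same for these 3 lists, which were too short for a set test. Gata2, a factor of progenitors and mast cells, stood at 1826 CPM with ZsGreen and rose to 2571 ± 371 CPM with ETV6 WT (0.49).

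The erythroid list was not called with ETV6 WT (camera adjusted p = 0.79). Of its genes, Hba-a1 rose from 35.2 ± 4.65 to 235 ± 52.3 CPM (2.74) and Hbb-bs from 0.305 to 8.07 CPM (4.70), while Tfrc, the transferrin receptor that brings iron into growing cells, fell from 330 to 183 CPM (-0.85). Globin copies share reads, so the division among them is uncertain. Among growth factors and their targets, Myc stood at 188 ± 5.76 CPM with ZsGreen, 112 ± 15.5 CPM with ETV6 WT, 176 ± 7.19 CPM with P214L and 106 ± 8.74 CPM with I209S P214L, values looked up afterwards. Il3ra, the alpha chain of the IL-3 receptor, stood at 64.7 ± 1.65, 80.8 ± 14.1, 66.7 ± 3.26 and 76.3 ± 6.63 CPM in the same order. Hras fell with I209S P214L (-0.47, adjusted p = 0.00483).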
